A study of Drosophila melanogaster with 4 samples.

How the data were processed

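The series measured where a GFP-tagged form of Stat92E lies on the genome of Drosophila melanogaster embryos, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). It holds 4 libraries. In 2 of them, chromatin was precipitated with ab290, a rabbit polyclonal antibody against GFP, and the other 2 are input DNA, the chromatin before precipitation. All 4 carry the label of embryos aged 12 to 24 h, and replicates are numbered in the labels. No label says whether they came from separate collections of embryos. Per the labels' protocols, embryos were cross-linked in 1.8% formaldehyde for 15 min. The protocol text names a fly line other than the tagged strain and describes egg laying for 12 h with no later ageing step in the part read here, so the stage is given as the sample labels state it.

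The data are 1 peak list for the whole series. Per the file headers, its coordinates are those of FlyBase release 5, and its source column names MACS, a program that compares read pileups in a ChIP library with those in a control. Per the submitters' processing notes, the tools were CASAVA 1.7.0.2 and 1.7.0.3, the aligner BWA and the peak caller MACS2, and the build was BDGP5. Versions of BWA and MACS2, the significance threshold, the treatment of reads that map to several places, and whether the 2 ChIP replicates were pooled are not given in the sources used here. Each peak has a start, an end and a score. The score is the deposited value of the authors' peak caller, and the file does not say whether it is a p or q on a log scale, a fold or a pileup. It was therefore compared only between peaks within this list. Differences in score units, and the share of a difference used as a bound below, depend on that unknown scale. The list has no value per library, so library depths are unknown here, no spread between replicates can be given, and ChIP cannot be set against input at a locus. Reads aligned to several copies of a repeat can raise or lower peaks there, depending on settings that are not stated.

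Release 5 divides the genome into the 5 main arms 2L, 2R, 3L, 3R and X, chromosome 4, heterochromatic sequence assigned to an arm (2LHet, 2RHet, 3LHet, 3RHet, XHet) or to the Y (YHet), unplaced scaffolds (U), further unplaced scaffolds of lower quality (Uextra), and the mitochondrial genome. The gene table at hand is of release 6, a different build, so no peak was assigned to a gene. The 22 gene lists and 8 sequence motifs written down before the data were examined were for that reason not tested, nor was the position of peaks relative to genes. The release 6 table served only to count the genes of each chromosome and to see which genes neighbour each other.

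Peak widths, covered lengths and scores were summarised per sequence. Shares of peaks have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Chromosome lengths of release 5 were not at hand, so densities use the span from the first to the last peak of a sequence. The number of peaks on each main arm, with peaks within 1 kb merged, was compared with the number expected from the arm's span by a two-sided exact binomial test. Scores were compared by two-sided permutation tests of the difference in medians with 100000 permutations. The distance from each peak midpoint to the nearest other midpoint was compared with 1000 random placements of as many points on the same spans. Positions were drawn evenly over each span (random placement test, two-sided). Score was related to width and to that distance by Spearman rank correlation across peaks, with 100000 permutations. P-values were adjusted by the Benjamini-Hochberg method within each family. Peaks are not independent replicates, and these tests describe this list, not the reproducibility of the experiment. The arm counts, the scores by arm, the clustering test and the correlations over all peaks were designed before the data were examined. The comparisons of chromosome 4, heterochromatic arm sequence and unplaced sequence with the main arms, the 2 blocks of wide peaks, and the correlations within the main arms and within Uextra and U were chosen after the data were seen.

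The peaks named were, by the rule fixed beforehand for the case without a gene annotation, the 10 of highest score, the highest of each arm, the 5 widest, and the 3 densest windows of 100 kb. The densest windows of the main arms and the highest peak of U were added afterwards. Alternatives were the 50% and the 25% of the peaks with the highest scores (of the arm peaks for arm counts, scores by arm and clustering, of the peaks of the arms and chromosome 4 for its density, of the arms, Uextra and U for the scores of unplaced sequence, and of the whole list otherwise), other merging distances, random placement within windows of 1 Mb, means in place of medians, removal of the 1% most extreme widths at either end, inclusion of heterochromatic and unplaced sequence and, added later, removal of the 2 blocks of wide peaks.

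The procedures were tested on simulated data with as many peaks as the 691 merged peaks of the main arms. The reported clustering and score tests used the 824 unmerged peaks, and more placements and permutations than these simulations. Even spreads were simulated with independent peaks, while the merged peaks of the list were clustered. The rate of false calls for the arm counts can therefore be higher in the list than in the simulations. With an even spread, 1 or more arms were called in 5.5% of 200 simulations, and with X given 1.5 times its share it was called in 96.5%. Clustering was called in 5% of 40 even spreads and in 100% of 40 simulations with 30% of the peaks placed within 5 kb of another. Shuffled scores gave a call for X in 2.5% of 40 simulations, and 5 score units added to X were called in 100%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.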

Results

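Stat92E is the STAT transcription factor of the Drosophila JAK/STAT pathway, which carries signals from cytokine receptors to the nucleus. To locate its binding in late embryos, chromatin was precipitated with an antibody against GFP from embryos labelled 12 to 24 h and Stat92E-GFP. The labels list a transgene that holds the genomic coding region of Stat92E. There were 2 ChIP libraries and 2 input libraries. The deposited result was a single list of 2380 peaks covering 1297 kb in total. The median peak width was 424 bp (interquartile range 310 to 626 bp) and widths ran from 201 to 15031 bp. The peak caller's scores ran from 6.79 to 498.08, with a median of 43.0. The list has no values per replicate, so none of the values below has a replicate error.

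Most of the peaks lay on sequence that release 5 of the genome does not place on a chromosome. Uextra, the collection of lower-quality unplaced scaffolds, held 1358 peaks, 57.1% of the list (exact 95% interval 55.0 to 59.1%), and U, the other unplaced scaffolds, held 78 (3.28%, interval 2.60 to 4.07%). The 5 main arms held 824 peaks (34.6%, interval 32.7 to 36.6%), chromosome 4 held 68 (2.86%, interval 2.23 to 3.61%), and the heterochromatic sequences assigned to an arm held 49 (2.06%, interval 1.53 to 2.71%). YHet held 2 peaks and the mitochondrial genome 1. The peaks covered 728 kb of Uextra and U and 514 kb of the main arms.

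Peaks on unplaced sequence also had the higher scores. The median score was 76.4 over the 1436 peaks of Uextra and U and 15.1 over the 824 peaks of the main arms, a difference of 61.3 score units (permutation test, two-sided, adjusted p = 3e-05, from the smallest p that 100000 permutations can give). Within unplaced sequence, the median was 77.3 on Uextra and 38.3 on U. Heterochromatic sequences assigned to an arm had a median score of 15.0, which differed from the main arms by -0.06 (adjusted p = 0.974), and chromosome 4 had a median of 17.5, a difference of 2.40 (permutation test, adjusted p = 0.15). Widths differed less: the median was 450 bp on Uextra and U, 382 bp on the main arms, 378 bp on chromosome 4 and 390 bp on the heterochromatic arm sequences. The 10 peaks of highest score were all on Uextra, with scores from 371.45 to 498.08 and widths from 482 to 1129 bp. The highest lay at 4484541 to 4485669 of Uextra with a score of 498.08, followed by 27271603 to 27272229 with 480.08 and 2831308 to 2831885 with 443.82. The highest peak of U, at 9538421 to 9538962, had a score of 350.79.

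**Figure D1:**
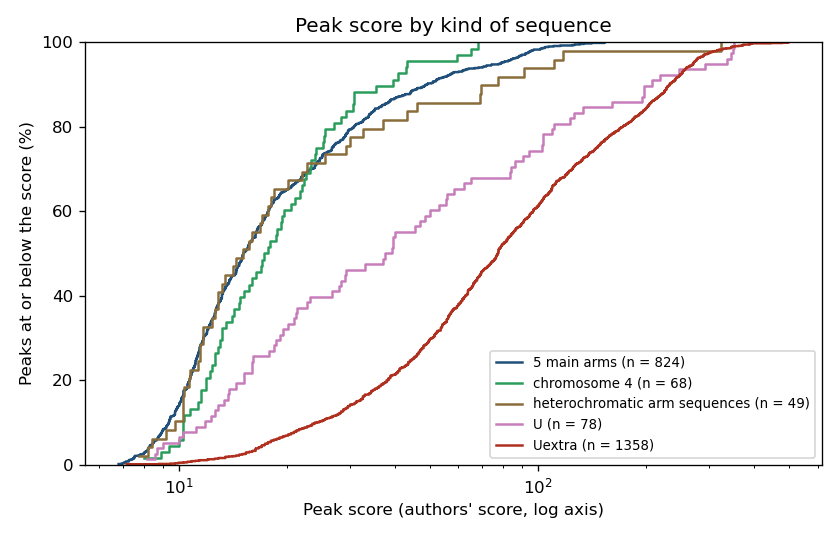
Cumulative share of peaks (vertical axis, %) at or below each score (horizontal axis, log scale, the authors' score), for the 5 main arms, chromosome 4, the heterochromatic arm sequences, U and Uextra, with 1 line per kind of sequence. The line of Uextra lies far to the right of that of the main arms (medians 77.3 and 15.1), while the heterochromatic arm sequences run close to the main arms up to their median of 15.0.

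The best peak of the main arms was outscored by 327 peaks elsewhere in the list. It lay on 3L at 16045214 to 16046406, was 1193 bp wide and had a score of 153.34. The highest peak of 2L lay at 7976403 to 7977174 (772 bp, score 140.94) and that of 2R at 15993774 to 15994326 (553 bp, score 130.76). On 3R it was the peak at 18276589 to 18278788 (2200 bp, score 102.89), and on X the peak at 14476991 to 14477851 (861 bp, score 94.39). The highest peak of chromosome 4 lay at 1316299 to 1317049 (751 bp, score 68.18). No gene or transcript feature is given for these positions, because the gene table used here is of another genome build.

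No main arm departed from its expected share of the peaks after adjustment. With peaks within 1 kb merged, the 5 arms held 691 peaks over spans of 119 Mb, or 5.82 per Mb. The ratio of observed to expected peaks was 0.92 on 2L (123 peaks, exact interval 0.78 to 1.08), 1.17 on 2R (143 peaks, 1.00 to 1.35), 0.88 on 3L (125 peaks, 0.74 to 1.03), 0.93 on 3R (151 peaks, 0.80 to 1.07) and 1.14 on X (149 peaks, 0.98 to 1.32). The adjusted p-values of the exact binomial test were 0.167 for 2R, 3L and X and 0.335 for 2L and 3R. Without merging, the ratio of 2R was 1.21 and passed the threshold (exact binomial test, adjusted p = 0.0267). The 177 unmerged peaks of 2R include 14 neighbouring peaks of a block described below, each counted as independent. Among the 25% of the arm peaks with the highest scores, X lay above its share with a ratio of 1.44 and 3L below it with 0.58 (exact binomial test, both adjusted p = 0.0238).

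No arm differed from the others in score by more than chance. The median score was 16.4 on 2L, 15.6 on 2R, 14.5 on 3L, 14.6 on 3R and 15.3 on X. The X differed from the 4 autosomal arms together by 0.205 score units (15.3 over 164 peaks and 15.1 over 660 peaks, permutation test, two-sided, p = 0.833). Each arm against the rest gave an adjusted p of 0.635 or above.

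Chromosome 4, a small and largely heterochromatic chromosome, was denser in peaks than any main arm. Its 68 peaks, 55 after merging within 1 kb, lay within a span of 1.29 Mb, which gives 42.8 merged peaks per Mb. This was 7.35 times the density of the main arms (exact 95% interval 5.48 to 9.69, exact binomial test, two-sided, p = 2.99e-28). The interval and the p treat merged peaks as independent. Those of the main arms still lay closer together than an even spread, so both understate the uncertainty. The heterochromatic arm sequences carried 7.57 unmerged peaks per Mb of span, U 8.19 and Uextra 47.5, against 52.9 on chromosome 4 and 6.94 on the main arms. With few peaks on a sequence, the span can fall well short of its length, which overstates the density. XHet had 3 peaks and 2LHet 4, so the heterochromatic arm sequences and the main arms cannot be ranked by these values.

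**Figure D2:**
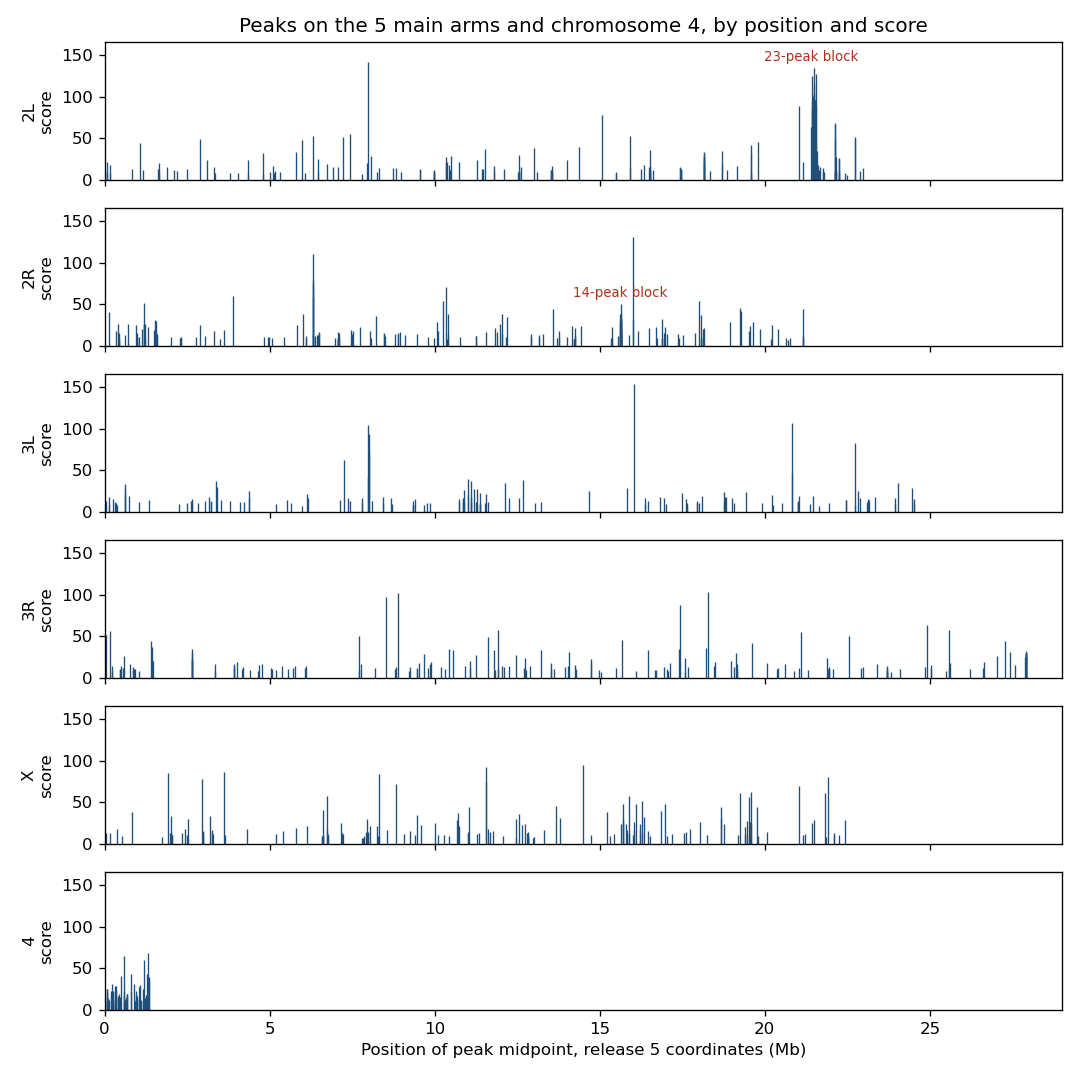
Every peak of the 5 main arms and chromosome 4 as a vertical line at its midpoint (horizontal axis, Mb, release 5) with its score as height (vertical axis, same scale in each panel). The block of 23 peaks near the right end of 2L stands out on 2L, the highest peak of these arms is on 3L with a score of 153.34, and the 68 peaks of chromosome 4 crowd a span of 1.29 Mb.

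Peaks on the arms lay closer together than an even spread would place them. The median distance from a peak to the nearest other was 22.5 kb over the 824 peaks, against 49.5 kb in random placements (95% of placements between 44.0 and 55.2 kb, permutation of positions, two-sided p = 0.002, the smallest that 1000 placements can give). The observed median was 5.44 kb on 2L, 15.2 kb on 2R, 27.7 kb on 3L, 34.6 kb on 3R and 23.5 kb on X, and random placement gave 46.6, 41.3, 59.5, 57.5 and 47.9 kb in the same order (permutation of positions, adjusted p = 0.002 on each arm). Part of the value of 2L came from the block of wide peaks described next, without which it was 12.7 kb against 53.6 kb at random. Much of the closeness lay between peaks under 1 kb apart: with these merged, the median was 45.8 kb against 59.0 kb at random (permutation of positions, p = 0.002). After peaks within 10 kb were merged, the median was 70.7 kb against 68.8 kb at random (permutation of positions, p = 0.657). Of the 1192 windows of 100 kb on the arms, 482 held a peak (40.4%) and 20 held 5 or more.

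The 5 widest peaks all lay in 2 blocks, 1 on 2L and 1 on 2R. The block of 2L ran from 21416413 to 21543672, a stretch of 127 kb in which 23 peaks covered 87.4% of the sequence. Its peaks had a median width of 4604 bp and scores from 33.63 to 134.19 (median 92.1), and the widest, at 21421004 to 21436034, was the widest of the whole list with 15031 bp. The block held 61.2% of all sequence covered by peaks on 2L. Outside it, the 2L peaks had a median width of 398 bp. The block of 2R ran from 15614904 to 15653900, where 14 peaks covered 90.5% of 39.0 kb, with widths up to 10849 bp and scores from 12.14 to 50.48 (median 30.1). It held 31.2% of the sequence covered on 2R. On the main arms the densest windows of 100 kb were the 2 that share the block of 2L, with 15 and 10 peaks, and the one with the block of 2R, with 14. Over the whole list the 3 densest windows were all near the end of Uextra, at 28700001 to 28800000, 28800001 to 28900000 and 28900001 to 29000000, with 57, 73 and 71 peaks.

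**Figure D3:**
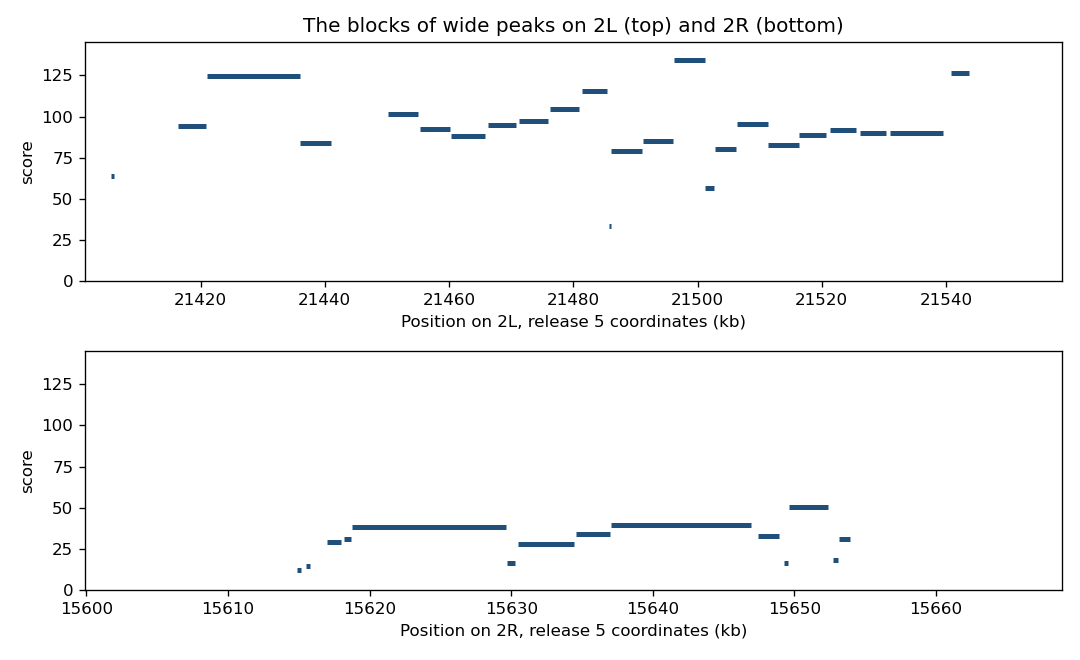
Peaks in and around the 2 blocks, each drawn to scale as a horizontal bar from its start to its end (horizontal axes, kb, release 5) at the height of its score (vertical axes). On 2L, 23 mostly wide peaks (median 4604 bp) follow one another over 127 kb with a median score of 92.1, and on 2R, 14 peaks of unequal width fill 39.0 kb with a median score of 30.1.

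Wider peaks scored higher. Across all 2380 peaks, the Spearman correlation of score with width was 0.504, and it was 0.692 within the main arms and 0.447 within Uextra and U (each adjusted p = 1.5e-05, from the smallest p that the permutations can give). It was lower among the peaks with the highest scores, at 0.148 in the highest 50% and 0.268 in the highest 25% of the list. The correlation of score with the distance to the nearest other peak was -0.17 across the 2379 peaks that share a sequence with another (adjusted p = 1.5e-05). Within the kinds of sequence it was 0.060 on the main arms (permutation test, adjusted p = 0.087) and -0.09 on Uextra and U (adjusted p = 0.000636), so the pooled value did not hold on the main arms. Uextra and U, with 1436 of the 2379 peaks, are collections of unplaced scaffolds. A distance there can run between unrelated scaffolds, so neither their value nor the pooled one describes distances on chromosomes. These are correlations across peaks of 1 list, and 6 were computed and adjusted together, apart from those of the alternative settings.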

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

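The peaks listed first lie on sequences that no comparison between kinds of sequence above used, although the correlations over the whole list include them. Of the tests below, those for a tandem repeat array, for genes on chromosome 4 and for heterochromatic sequence assigned to the arms were chosen after the values were seen. The list has no peaks called on input alone, so there is no control level for any of them.

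The single peak on the mitochondrial genome, at 17953 to 19242, was 1290 bp wide and had a score of 45.64, above 732 of the 824 peaks of the main arms. The 2 peaks of YHet, heterochromatic sequence assigned to the Y chromosome, lay at 4477 to 4811 with a score of 127.9 and at 137056 to 137527 with a score of 115.83. They exceeded 820 and 818 of the 824 peaks of the main arms.

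The first pattern is the pair of blocks on 2L and 2R. An independent, even scatter of peaks over the arms is argued against for both blocks. Random placements of the arm peaks never put more than 8 in a window of 100 kb on any arm. The densest window of 2L held 15 (permutation of positions, p = 0.001, the smallest that 1000 placements can give). The window with the block of 2R held 14. Outside the blocks the peaks of the arms were clustered as well, so the test cannot decide about ordinary clustered peaks falling together. A tandem repeat array is in line with the block of 2L, where peak starts kept a period of 5010 bp with a phase coherence of 0.856, against a 95th percentile of 0.750 when the widths and gaps of its peaks were shuffled (permutation test, 2 of 1000 orders as high, p = 0.003), though only 10 of the 22 spacings lay between 4900 and 5200 bp. On 2R the coherence was 0.532 against 0.605. Only periods of 1 to 10 kb were scanned, so the test could not detect a shorter repeat unit, and an array stays open. In the release 6 gene table, 2L has 1 array of 119 neighbouring replication-dependent histone genes and pseudogenes, with 23 copies of His1 and only 20 small RNA genes among them, and 2R has 96 5S rRNA genes with 4 5S rRNA pseudogenes and no other gene among them, so these arrays are candidate identities of the blocks, which coordinates of a shared build would settle; no biological explanation was tested.

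The second pattern is the density of chromosome 4. A few tight clusters of peaks do not account for it, since with peaks within 10 kb merged the density was still 5.88 times that of the main arms (exact interval 4.12 to 8.17). A larger number of genes does not either: chromosome 4 had 48.2 merged peaks per 100 genes of the release 6 table (interval 36.3 to 62.8), and the main arms 3.51 to 5.52. Repeats on this chromosome, its chromatin and Stat92E binding itself stay open as untested.

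The third pattern is the excess of score on unplaced sequence. Heterochromatic sequence assigned to the arms did not show the excess as a set, although its highest peaks, with 322.43 on 3RHet, 117.65 on 2LHet and 111.04 on 3LHet, lie in the upper range of the list: the difference in median score between the heterochromatic arm sequences and the main arms was -0.06 (bootstrap 95% interval -2.76 to 3.30), far from the 30.6 that would be 50% of the difference seen on Uextra and U. The 2 peaks of YHet, with scores of 127.9 and 115.83, go the other way and are too few for a test, so heterochromatin of the Y stays open. The last megabase of Uextra alone does not account for the excess, since without that megabase the difference was 50.9 (interval 47.0 to 54.5). Wider peaks do not either, since within quartiles of width the difference averaged 66.8 (interval 61.4 to 72.3). The bootstrap intervals, from 2000 draws, treat single peaks as independent. The 1436 peaks of Uextra and U became 1169 when those within 1 kb were merged, so the intervals are likely too narrow. Reads shared between copies of a repeat, copies missing from the assembly and DNA of other organisms in Uextra stay open, as neither sequence nor mapping quality was at hand, and no biological explanation was tested.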

How the results depend on the processing

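Of 72 values recomputed for 13 results, 62 kept their side of the threshold or stayed within the interval of the main value. The 62 include values from sets selected by the score that is compared, which are no check, as stated below. Also among the 62, ratios that were not past the threshold crossed 1 for 2L without merging (1.07) and among the highest 25% (1.09), and for 2R among the highest 25% (0.987). The removal of the 2 blocks of wide peaks, the restriction of the score correlations to the main arms or to Uextra and U, and all alternatives for the density of chromosome 4 and for the scores of Uextra and U were chosen after the data were seen. The share of peaks outside the main arms and chromosome 4 was 62.5%. It rose to 91.2% among the 50% of the peaks with the higher score and to 97.1% among the highest 25%. In the same sets the median width went from 424 bp to 522.5 and 516 bp. The rise in the share follows from the higher scores of Uextra. The rise in width goes with the correlation of score with width over all peaks, 0.504, whose cause was not tested. Among the highest 25% of the arm peaks, the ratio of observed to expected peaks passed the threshold for X with 1.44 and for 3L with 0.58, and without merging it did so for 2R with 1.21; the cause was not tested. The clustering ratio of 0.455 became 1.03 when peaks within 10 kb were merged first, which removes the short distances by construction, and 0.777 with merging within 1 kb. The correlation of score with width, 0.504 over all peaks, stayed past the threshold but was 0.148 and 0.268 in the highest 50% and 25%. The correlation of score with spacing, -0.17 over all peaks, was -0.063 in the highest 25% (no longer past the threshold) and 0.060, of the opposite sign and not past the threshold, on the main arms. The density ratio of chromosome 4 ranged from 5.88 to 9.08, past the threshold throughout. Without the last megabase of Uextra, the difference in median score of Uextra and U was 50.9, and the difference in means over all peaks was 79.5. The score difference in medians was 61.83 with peaks within 1 kb merged and 61.55 without the 2 blocks. Its values of 31.8 and 62.7 in the highest 50% and 25%, with 91 and 14 arm peaks left, select peaks by the score that is compared and are no check of it, and the same holds for the scores by arm and the score correlations in these sets. Leaving out replicates was not run, since the list has no values per replicate. No paired analysis was possible because the list gives no value for any single library. The threshold of the peak caller and the depth of the libraries are unknown, so sites below the threshold cannot be told from unbound sites.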

Other observations

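The test of the proximal ends of the arms was chosen after the map of peaks was seen, and that of the distal ends before its result. Peaks were more frequent toward the bases of the arms, where euchromatin passes into pericentromeric heterochromatin. Within 2 Mb of the base, the 5 arms held 92 merged peaks where an even spread over the spans gives 58.7, a ratio of 1.57 (exact interval 1.28 to 1.89, exact binomial test, two-sided, p = 2.09e-05). Peaks merged within 1 kb were still clustered, so this interval, which treats them as independent, is likely too narrow and the p too small. The counts were 26 against 10.7 expected on 2L, 24 against 13.6 on 2R, 18 against 10.8 on 3R, 13 against 10.2 on 3L and 11 against 13.3 on X, so the X did not share the direction. Without the blocks of wide peaks the ratio was 1.53, without the whole of 2L it was 1.38 (exact binomial test, p = 0.01), and with peaks within 10 kb merged it was 1.44 (p = 0.00192). The distal ends showed no such excess, with 57 peaks against 58.7 expected, a ratio of 0.971 (interval 0.74 to 1.24, exact binomial test, p = 0.89). A candidate explanation is the higher repeat content near the bases, which was not measured here.

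Uextra itself was uneven along its coordinates, which run over unplaced scaffolds and so give no position on a chromosome. Its part beyond 28 Mb, about 1.00 Mb long, held 418 of the 1358 peaks (30.8%), or 416 per Mb, with a median score of 109. The part before it held 34.1 peaks per Mb with a median score of 67.7.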
